A study of Mus musculus with 5 samples.

How the data were processed

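Total RNA was pooled from whole mice aged 1 day and, separately, from the colon of mice aged 8 weeks, both of the C57BL/6 strain per the labels. The 2 pools were mixed so that colon made up 0%, 25%, 50%, 75% or 100% of the total RNA. From each mix, 10 ng of total RNA was amplified in 2 rounds by T7 in vitro transcription and hybridised to an Affymetrix mouse expression array, per the labels' protocols. There was 1 array per mix, 5 in all, and no replicate of any mix, so the number of arrays limits the precision of every value. Each sample was grouped by the colon share in its labels.

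The deposited table holds the authors' log2 signals for 22690 probe sets, made with RMA (background correction, quantile normalization and median polish over the arrays) per the submitters' processing notes. The version of that tool is not given in the sources used here. The scale was checked on the values, whose array medians lay between 6.83 and 6.92. RMA's median polish gave exactly tied values between arrays in 9158 probe sets (40.5%), of which 66 held 1 value on all 5 arrays. The 64 control probe sets were described separately, and 22626 probe sets were tested without a filter on signal. The annotation paired 20380 of these with 1 gene, 691 with several and 1555 with none listed, and probe sets with several genes were left unnamed. Gene symbols were checked through their gene identifiers against a RefSeq table of assembly GRCm38.p6, in which 20364 probe sets were matched, and 12393 distinct genes were named.

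For each probe set the log2 signal was regressed on the colon share of total RNA (from 0 to 1) over all 5 arrays with limma 3.58.1 in R 4.3.3. The slope is the fitted log2 difference, colon minus whole mouse, and its variance was moderated by eBayes with 3 residual degrees of freedom. P-values were 2-sided and Benjamini-Hochberg adjusted over all probe sets tested, with a threshold of 0.05. All arrays came from the same 2 RNA pools, so these p-values say nothing of the spread between mice. They measure technical spread together with any bend of the signals away from a straight line on the log2 scale. Tissue and age differed together between the pools. Genes with several probe sets were represented by the one with the highest mean signal.

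Before the data were examined, 41 gene lists were fixed for cell types, tissues and pathways. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 41 lists, and again with the correlation estimated from the data. The number of members past the threshold was counted with the adjustment over all probe sets and with the adjustment over the list alone. Genes named in the text followed a rule that was also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls that passed the threshold with all 5 values in strict order. From each list it took the 3 members past the threshold with the largest change and the brightest member not past it. It also took all reference genes and sex-linked genes.

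The difference between the undiluted RNAs was described by size alone, since each had 1 array. The colon share of a mixture was estimated on the linear intensity scale as its distance from the whole mouse array divided by the distance between the undiluted arrays. The median was taken over probe sets that differed at least 2-fold, with a 95% bootstrap interval from 1000 draws of probe sets. Agreement of the mixtures with linear mixing was described by the standard deviation of the log2 deviation from the weighted mean of the undiluted intensities. The same regression was run for all 60 orders of the 5 arrays, an order and its reverse being the same test.

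The fit was tested on simulated data for the comparison along the dilution, with 22626 probe sets and normal noise whose standard deviations were those of the residuals, shuffled over probe sets. With 200 probe sets changed, 24% of those changed by 1 log2 unit, 64% of those changed by 2 and 94% of those changed by 4 were recovered, with 4 false calls. With 4409 changed, these shares were 76.3%, 94.6% and 98.7%, and 4.88% of the calls were false. The simulated changes were straight lines on the log2 scale with noise unrelated to their size, so these shares may not hold for the data. There, 321 of 1327 probe sets at least 4-fold apart between the undiluted arrays missed the threshold. Simulated mixtures of the undiluted arrays at 25%, 50% and 75%, with noise of 0.1 log2, gave estimated shares of 25.4%, 49.9% and 74.7%. In the data the deviation from linear mixing was larger, with standard deviations of 0.25, 0.23 and 0.18 log2. Strict order held in 94.8% of the simulated 2-fold probe sets but in 69.2% of those in the data. The share estimate was thus not checked at the noise of the data. Of 820 random gene lists tested with camera on simulated data, 1.83% had a p-value under 0.05. The simulated noise was independent between probe sets, whereas the estimated correlation in the data reached 0.806 in colonocyte genes. That share therefore does not show how often camera passes correlated lists by chance.

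Alternatives covered the scale of the fit, further centring or quantile normalization, a filter on dim probe sets, the variance model, the threshold, the choice of probe sets, the covariate and leaving out each array in turn. The choice of probe sets by the 25% and 75% mixtures was planned without a threshold. It was first run at 0.5 log2 and then at 2-fold, the threshold of the main estimate, after the first result had been seen; both are given. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Arrays of the same mixes run elsewhere were not analysed here.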

Results

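The series is a dilution of 1 RNA pool into another, made to compare array platforms on mixes of known composition. Each of 5 arrays carried 1 mix of RNA from the whole newborn mouse and RNA from adult colon, at colon shares of 0%, 25%, 50%, 75% and 100%. None of the mixes had a replicate array among these samples. The arrays were close in scale, with median log2 signals of 6.90, 6.92, 6.88, 6.86 and 6.83 in order of rising colon share. Below, a gene "rose" or "fell" when its signal changed with rising colon share past the test's threshold, and values on the 5 arrays are given in that order.

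The 2 RNAs differed in many genes, and the signals followed the mixing. By camera at a preset correlation, lists of intestinal epithelium were higher in colon and lists of muscle, liver, skin and skeleton in whole mouse. None of the 41 lists passed with an estimated correlation (lowest adjusted p = 0.204). Of 22626 probe sets, 4409 (19.5%) passed the limma test at an adjusted p of 0.05, of which 1953 rose and 2456 fell. Among 12393 genes, 1215 rose and 1797 fell. The largest rises among genes in strict order were those of Car8, a carbonic anhydrase-related protein (3.71 log2, SE 0.79, adjusted p = 0.0359), Atp2c2, a secretory-pathway calcium pump (3.59), and Cdx1, an intestinal transcription factor (3.58). AW112010 (3.55), Dio1, a deiodinase of thyroid hormone (3.50), Cftr, the epithelial chloride channel (3.40, and 0.13 in its other probe set), and Prom1, a membrane glycoprotein of epithelial progenitors (3.38), came next. They were followed by the sulfotransferase Sult1c2 (3.33), the sodium-coupled monocarboxylate transporter Slc5a8 (3.33) and the sulfotransferase Sult1b1 (3.30).

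Among the genes that passed in strict order, the largest falls were larger than the largest rises. Kng1, the liver's kininogen, fell by 7.10 log2 (SE 1.68, adjusted p = 0.0464), with signals of 12.10, 11.45, 10.82, 9.48 and 4.21. Tnnc1, troponin C of slow and cardiac muscle, fell by 6.26 log2, Bhmt, a liver methyltransferase, by 6.21 and Itgb1bp2, a muscle integrin-binding protein, by 6.15. Fibrinogen alpha (Fga) fell by a fitted 6.03, its colon signal of 3.41 lying at the level of the poly-A spikes (3.24 to 3.54) and leaving the size of its fall inexact, the Z-disc protein Actn2 by 5.99, the myosin light chain Myl3 by 5.97 and the calcineurin-binding muscle protein Myoz2 by 5.85. The cornified envelope gene Lce1d fell by 5.78 and sarcolipin (Sln), a regulator of the muscle calcium pump, by 5.76 in its brightest probe set (its other had a slope of −0.12). A fitted change of at least 8-fold was seen in 32 probe sets that rose and 286 that fell. Of 1327 probe sets at least 4-fold apart between the undiluted RNAs, 321 did not pass, 260 of them higher in colon and 61 in whole mouse, so these counts leave out more of the large differences toward colon. Examples, chosen after their values were seen, are Saa1, an acute-phase protein, with 4.64 in whole mouse and 12.67 in colon (fitted 6.80 log2, adjusted p = 0.12), and the carbonic anhydrase Car1, with 6.62 and 14.02 (5.96, adjusted p = 0.174).

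The number of calls fell from 4409 whenever an array was left out. It was 1492 without the whole mouse array, 2998 without the 25% mixture and 1919 without the 50% mixture. Without the 75% mixture it was 1365, and without the colon array 997. Each such fit had fewer residual degrees of freedom, so the fall alone cannot show that calls rested on single arrays. At an unadjusted limma p under 0.05 the number fell less, from 7866 to between 5874 (without the colon array) and 7680 (without the 25% mixture). Of the 122 named genes that passed, 43 did so without the whole mouse array, 49 without the 25% mixture, 40 without the 50% mixture, 34 without the 75% mixture and 57 without the colon array. The 16 named genes that passed without each array in turn included none of the 20 largest rises and falls above, which passed in at most 2 of the 5 fits that left out an array, and 5 of which (Atp2c2, Cdx1, AW112010, Sult1c2 and Slc5a8) passed in none. Among the 16 were Mfap2, Mfap5, Thbs2, Icam2, Sox18, Cdh16, Cubn, Ctrb1, Hspb1 and Lcn2. All 16 fell, so no named gene that rose passed without each array in turn. Centring the arrays on their medians turned the split of 1953 rises and 2456 falls into 3148 and 2325.

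**Figure D1:**
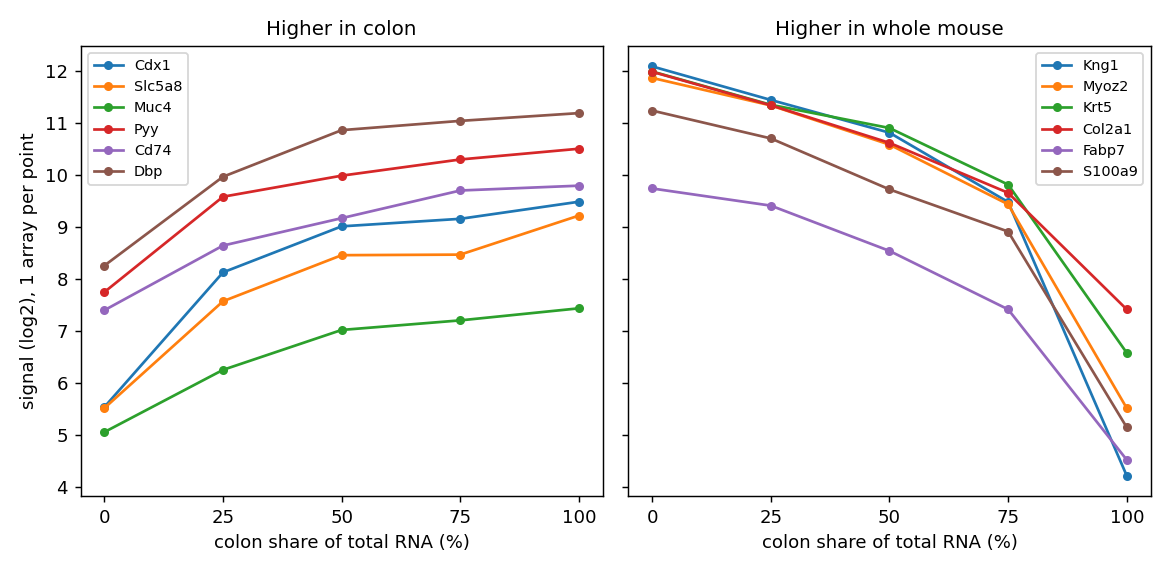
Log2 signal (vertical axis) against the colon share of total RNA in percent (horizontal axis) for 6 genes that rose and 6 that fell, with 1 array per point and no error bars because no mix had a replicate. Cdx1 went from 5.53 on the whole mouse array to 9.49 on the colon array and Kng1 from 12.10 to 4.21, with 9.48 at 75% colon.

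The epithelium of the colon stood out among the lists higher in colon. Of 37 measured genes of absorptive colonocytes, 9 rose and none fell (33 and 1 adjusted over the list alone), with a median fitted difference of 3.13 log2 (camera adjusted p = 3.7e-09). Cdx2, a partner of Cdx1 in intestinal identity, rose by 3.13 log2 (SE 0.68, adjusted p = 0.0374), and Slc5a8, which takes up short-chain fatty acids, by 3.33. Lgals4, a lectin of intestinal epithelium, had signals of 11.40 in whole mouse, 13.60 at 25% colon and 13.92 in colon (adjusted p = 0.129). Of 21 genes of goblet cells and mucins, 6 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 2.89 (camera adjusted p = 4.7e-06). Tpsg1 (2.64), a serine protease, the goblet cell transcription factor Spdef (2.64) and the membrane mucin Muc4 (2.29) rose, while trefoil factor Tff3, already at 12.58 in whole mouse, reached 13.88 in colon (adjusted p = 0.121). Both lists had an adjusted p of 0.349 with an estimated correlation.

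Hormone-producing cells, crypts and detoxifying enzymes followed the same direction. Of 19 enteroendocrine genes, 7 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.51, camera adjusted p = 0.0231). Glucagon (Gcg), the precursor of GLP-1 in gut, rose by 3.18 log2, the granin Chgb by 2.68 and peptide YY (Pyy) by 2.50, while the processing enzyme Cpe stayed between 10.51 and 10.79 (adjusted p = 0.625). Of 13 crypt and stem cell genes, 4 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.56, camera adjusted p = 0.0438). Prom1 and the chloride cotransporter Slc12a2 (2.08) rose, whereas the receptor Tnfrsf19 fell by 2.23 log2 in its brightest probe set (0.06 at the highest of 3), and Ephb3 lay between 10.07 and 10.49 (adjusted p = 0.655). Of 22 genes of xenobiotic and steroid metabolism in gut, 8 rose and none fell (17 and 2 adjusted over the list alone; median 1.48, camera adjusted p = 7.9e-05), among them the carboxylesterase Ces2e (2.96) and the cytochrome Cyp3a13 (2.55). The alcohol dehydrogenase Adh1 had 12.29 in whole mouse and 13.39 in colon (adjusted p = 0.0833). These 3 lists had an adjusted p of 0.325 with an estimated correlation. Without the whole mouse array the adjusted p of enteroendocrine cells was 0.0694 and that of crypt cells 0.0746, the latter also 0.0633 without the 75% mixture.

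Lists of immune genes gave different counts and were not tested against each other. Of 10 genes of MHC class II antigen presentation, 5 rose and none fell (7 and 0 adjusted over the list alone; median 1.29, camera adjusted p = 0.0026), among them H2-Ab1 (2.45), the invariant chain Cd74 (2.34) and cathepsin S (Ctss, 2.14). H2-Aa had 8.46 in whole mouse and 11.15 in colon (adjusted p = 0.0662). Of 24 interferon-induced genes, 9 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 8.0e-05), with the immunoproteasome subunit Psmb9 (2.16) and the transcription factors Irf1 (2.03) and Irf7 (1.53) as examples. Oas1a, a sensor of double-stranded RNA, had 8.64 and 10.90 (adjusted p = 0.0513). The adjusted p of both lists was 0.204 with an estimated correlation. Of 16 mucosal defence genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.83, camera adjusted p = 0.0061, and adjusted p = 0.325 with an estimated correlation). The tryptophan-degrading enzyme Ido1 (2.36) and the cytokine Il18 (1.44) rose, and the siderophore-binding Lcn2, also a neutrophil granule gene, fell by 3.69 log2. Lypd8, which keeps bacteria off the colon epithelium, had 10.62 in whole mouse and 13.89 in colon (adjusted p = 0.156).

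Plasma and B cell genes did not pass as a list (camera adjusted p = 0.0525), with 3 of 15 rising and 1 falling (4 and 2 adjusted over the list alone). The B cell linker Blnk rose by 3.25 log2 and the secretory factor Xbp1 by 1.18 (0.15 at the lowest of 4 probe sets), Prdm1 fell by 0.82, and the IgA heavy chain Igha had 6.81 in whole mouse, 12.79 at 25% colon and 13.59 in colon (adjusted p = 0.128). Among 14 T cell genes none rose and Thy1, also a neuronal surface protein, fell by 1.72 (0 and 1 adjusted over the list alone; camera adjusted p = 0.96), with the kinase Zap70 between 8.57 and 9.23 (adjusted p = 0.655). Genes of macrophages and mast cells went both ways, with 3 of 16 rising and 6 falling (3 and 6 adjusted over the list alone; camera adjusted p = 0.275). The endotoxin receptor Cd14 rose by 2.55 log2, the mast cell protease Cpa3 fell by 3.95 and the adaptor Tyrobp by 1.66, while lysozyme Lyz2 lay between 10.09 and 10.32 (adjusted p = 0.332).

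Smooth muscle, the clock and early-response genes were higher in colon as lists. Of 19 visceral smooth muscle genes, 5 rose and 1 fell (14 and 2 adjusted over the list alone; median 0.74, camera adjusted p = 0.0014). Calponin (Cnn1) rose by 2.26 log2 and the myosin kinase Mylk by 1.68, and transgelin (Tagln) had 10.79 and 13.19 (adjusted p = 0.0603). The brightest probe set of tropomyosin Tpm1 fell by 2.10, but the slopes of its 3 probe sets ran from −2.10 to 1.88. The list's adjusted p was 0.348 with an estimated correlation. Of 14 circadian output genes, 7 rose and none fell (9 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 7.2e-04, and adjusted p = 0.204 with an estimated correlation), among them Dbp (2.78), Per2 (2.28) and Nr1d2 (2.20), with Per1 at 8.65 and 9.18 (adjusted p = 0.0671). Of 28 immediate-early and heat-shock genes, 7 rose and 2 fell (13 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.0066, and adjusted p = 0.300 with an estimated correlation). Fos (1.91) and Atf3 (1.51) rose, the small heat-shock protein Hspb1 fell by 2.23, and Hspa8 had 12.23 and 12.68 in its brightest probe set (adjusted p = 0.291). The slopes of the 4 Hspa8 probe sets ran from −0.22 to 1.88. Among the clock genes, the other probe sets of Per2 and Nr1d2 had slopes of 0.33 and 0.18.

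In the enteric neuron and glia list 2 of 14 genes rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.227). The gut neuropeptide Vip rose by 2.81 log2, the pan-neuronal gene Stmn2 fell by 2.58 and Uchl1, another, fell with an adjusted p of 0.00495, and Npy had 8.04 in whole mouse and 6.96 in colon (adjusted p = 0.0516). Of 18 genes of fatty acid oxidation and ketogenesis, 1 rose and 2 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.316). The monocarboxylate transporter Slc16a1 rose by 1.76, the thiolase Acaa2 fell by 1.32 and the dehydrogenase Acadvl by 0.83, while Hadh lay between 12.98 and 13.12 (adjusted p = 0.824).

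Muscle and liver gave the largest shifts toward the newborn. Of 39 skeletal muscle genes, 29 fell and none rose (38 and 0 adjusted over the list alone), with a median of −4.68 log2 (camera adjusted p = 5.9e-12). Actn2, Myoz2 and the Z-disc protein Myot (−5.61) were the largest falls that passed, and skeletal actin Acta1 had 13.95 in whole mouse, 12.91 at 75% colon and 6.63 in colon (adjusted p = 0.115). Of 20 heart genes, 13 fell and none rose (14 and 0 adjusted over the list alone; median −3.51, camera adjusted p = 3.9e-05), led by Tnnc1, Myl3 and Sln, and cardiac actin Actc1 had 12.73 and 7.16 (adjusted p = 0.0709). Of 33 liver genes, 22 fell and none rose (32 and 0 adjusted over the list alone; median −5.03, camera adjusted p = 6.3e-10). Vitronectin (Vtn) fell by 5.26 log2 beside Kng1 and Fga, and albumin (Alb) had 13.70 in whole mouse, 12.94 at 75% colon and 6.48 in colon (adjusted p = 0.136). With an estimated correlation the adjusted p was 0.325 for skeletal muscle, 0.300 for heart and 0.325 for liver.

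By camera, lists of other digestive organs were higher in whole mouse. Of 16 genes of the pancreas, 13 fell and 1 rose (13 and 1 adjusted over the list alone; median −2.38, camera adjusted p = 8.1e-07). The lipase-related Pnliprp1 fell by 4.65 log2, chymotrypsinogen Ctrb1 by 4.46 and the elastase Cela3b by 3.86, while the islet peptide Iapp had 8.75 and 7.99 (adjusted p = 0.385). Of 17 stomach and small intestine genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone; median −0.75, camera adjusted p = 0.0039). The fatty acid-binding protein Fabp1 fell by 5.76 log2, lactase (Lct), the milk-sugar enzyme of the suckling gut, by 4.46 and the gastric peptide Gkn1 by 2.68, and Apoa4 had 12.90 and 6.45 (adjusted p = 0.0682). The estimated correlation gave an adjusted p of 0.204 for pancreas and 0.325 for stomach and small intestine.

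**Figure D2:**
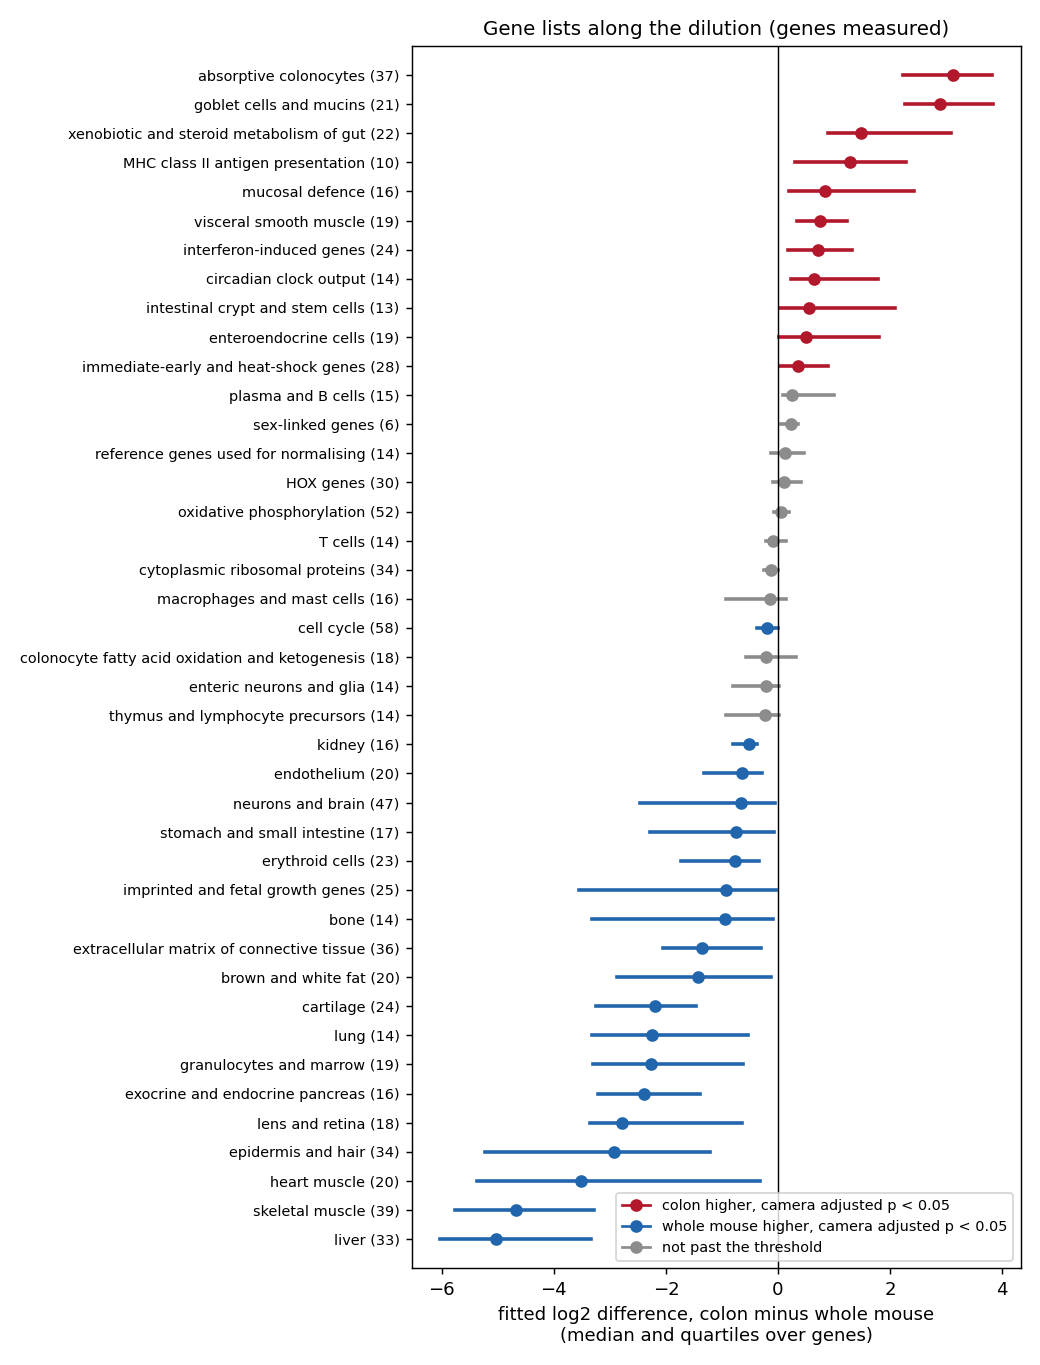
Median (point) and quartiles (bar) over genes of the fitted log2 difference, colon minus whole mouse (horizontal axis), for the 41 gene lists (vertical axis, genes measured in brackets), coloured by camera at the preset correlation. Absorptive colonocytes lie at 3.13 and liver at −5.03, and with an estimated correlation no list passed.

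Genes of skin, skeleton and connective tissue were higher in the whole newborn. Of 34 genes of epidermis and hair, 21 fell and none rose (29 and 0 adjusted over the list alone; median −2.93, camera adjusted p = 6.3e-10). The basal keratins Krt14 and Krt5 fell by 5.67 (−0.45 at the highest of 3 probe sets) and 4.95 log2 and the lectin Lgals7 by 5.60, and the suprabasal keratin Krt10 had 13.63 and 7.35 (adjusted p = 0.116). Of 24 cartilage genes, 18 fell and 1 rose (20 and 2 adjusted over the list alone; median −2.19, camera adjusted p = 7.0e-08), among them fibromodulin (Fmod, −5.10), chondromodulin (Cnmd, −4.62) and type II collagen (Col2a1, −4.34), with Col9a1 at 9.91 and 4.57 (adjusted p = 0.0527). Of 14 bone genes, 7 fell and none rose (7 and 0 adjusted over the list alone; median −0.94, camera adjusted p = 0.0095). Bone sialoprotein (Ibsp), at the level of the poly-A spikes in colon (3.38), fell by a fitted 5.13, a size that is inexact for that reason, the osteoclast protease Ctsk by 3.78 and Col1a1 by 3.40, while the phosphatase Acp5 had 10.81 and 11.11 (adjusted p = 0.133). Of 36 extracellular matrix genes, 24 fell and none rose (25 and 1 adjusted over the list alone; median −1.35, camera adjusted p = 3.6e-09), with the microfibril genes Mfap2 (−3.31) and Mfap5 (−2.48) and thrombospondin Thbs2 (−2.58), and with Tgfbi at 10.98 and 10.73 (adjusted p = 0.394). These 4 lists had an adjusted p of 0.204 with an estimated correlation.

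Genes of blood and fat showed the same direction. Of 23 erythroid genes, 12 fell and none rose (15 and 1 adjusted over the list alone; median −0.76, camera adjusted p = 3.9e-05). The haem synthesis enzyme Alas2 fell by 4.18 log2, the band 3 anion exchanger Slc4a1 by 4.01 (−0.06 at the highest of 3 probe sets) and Hemgn by 2.92, whereas Car2, a carbonic anhydrase also made by colonocytes, had 10.66 in whole mouse and 13.58 in colon (adjusted p = 0.069). Of 19 granulocyte and marrow genes, 14 fell and none rose (14 and 0 adjusted over the list alone; median −2.27, camera adjusted p = 2.0e-06), including the calgranulins S100a9 (−5.60) and S100a8 (−5.54) and the antimicrobial peptide Camp (−4.18). Of 20 fat genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone; median −1.43, camera adjusted p = 3.1e-04). The brown fat genes Cidea and Ucp1, the uncoupling protein of heat production, fell by 5.17 each and Fabp3 by 4.85, with resistin (Retn) at 8.85 and 8.23 (adjusted p = 0.156). With an estimated correlation the adjusted p of these 3 lists was 0.204.

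Of 47 genes of neurons and brain, 21 fell and 1 rose (23 and 1 adjusted over the list alone; median −0.66, camera adjusted p = 5.1e-06). The radial glia gene Fabp7 fell by 4.98 log2, the growth cone protein Crmp1 by 4.32 and the neuronal membrane protein Gpm6a by 3.83, and Tubb2b had 10.30 and 5.88 (adjusted p = 0.0991). Of 18 lens and retina genes, 13 fell and none rose (13 and 0 adjusted over the list alone; median −2.78, camera adjusted p = 4.7e-07), with the lens crystallins Cryga (−4.71), Crygd (−4.39) and Cryba1 (−4.30), and with Crybb2 at 7.29 and 6.74 (adjusted p = 0.297). Of 14 lung genes, 8 fell and none rose (10 and 0 adjusted over the list alone; median −2.25, camera adjusted p = 1.3e-05), led by the airway secretoglobins Scgb3a2 (−4.21) and Scgb1a1 (−3.99) and the surfactant protein Sftpa1 (−3.53), with Hopx at 11.50 and 11.10 (adjusted p = 0.146). With an estimated correlation the adjusted p of these 3 lists was 0.204.

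Of 16 kidney genes, 4 fell and none rose (5 and 0 adjusted over the list alone; median −0.52, camera adjusted p = 0.0010). The tubular genes Cdh16, Cubn and Umod fell by 2.12, 1.70 and 1.23 log2, and the water channel Aqp1 had 9.15 and 8.70 (adjusted p = 0.231). Of 20 endothelial genes, 10 fell and none rose (12 and 0 adjusted over the list alone; median −0.65, camera adjusted p = 8.7e-05), among them Icam2 (−2.48), Sox18 (−1.80) and VE-cadherin (Cdh5, −1.71), with Plvap at 8.64 and 8.82 (adjusted p = 0.598). The other probe set of Umod had a slope of −0.22 and that of Cdh5 −0.12. With an estimated correlation the adjusted p was 0.257 for kidney and 0.217 for endothelium.

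Genes of fetal growth were higher in the newborn pool. Of 25 imprinted and fetal growth genes, 10 fell and none rose (14 and 0 adjusted over the list alone; median −0.92, camera adjusted p = 4.4e-04, and adjusted p = 0.204 with an estimated correlation). The amino acid transporter Slc38a4 fell by 5.50 log2, the brightest probe set of the zinc-finger gene Plagl1 by 4.33 (its other had a slope of 0.08) and Dlk1 by 4.10, and the noncoding RNA Meg3 had 13.26 and 10.26 (adjusted p = 0.0597). Of 58 cell cycle genes, 5 fell and 1 rose (4 and 1 adjusted over the list alone; median −0.19, camera adjusted p = 0.0284). Stmn1 fell by 1.26 and the replication helicase subunit Mcm7 by 0.84, Cks2 rose by 0.74, and Bub3 lay between 10.96 and 10.98 (adjusted p = 1). That list had an adjusted p of 0.325 with an estimated correlation and of 0.0615 without the 75% mixture. Of 14 thymus genes, 3 fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0954), namely Arpp21 (−2.03 in its brightest probe set, 0.03 at the highest of 3), the recombinase Rag1 (−1.48) and Bcl11a (−1.48), with Cd1d1 at 8.62 and 8.22 (adjusted p = 0.0929).

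Of 30 HOX genes, which set position along the body axis, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0946). The risers were Hoxa9 (1.63 log2, and 0.23 in its other probe set), Hoxa10 (1.35) and Hoxb6 (1.28), and the posterior gene Hoxb13 had 4.38 in whole mouse, 8.71 at 25% colon and 9.80 in colon (adjusted p = 0.0906). Housekeeping lists moved little. Of 34 cytoplasmic ribosomal protein genes none passed, and none did so adjusted over the list alone (median −0.13, camera adjusted p = 0.0946), with Rpl41 between 14.15 and 14.29 (adjusted p = 0.424). Of 52 oxidative phosphorylation genes 1, Cox5a, rose by 0.48 and none passed adjusted over the list alone (camera adjusted p = 0.228), with Cox5b between 13.98 and 14.10 (adjusted p = 0.468).

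Reference genes differed in how steady they were. Of 14, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.246). Tubb5 fell by 1.71 log2 (SE 0.20, adjusted p = 0.0093), B2m rose by 1.14 and the brightest probe set of Tbp by 0.59, although the slope of the other Tbp probe set was −0.18. The rest did not pass, with fitted differences of 0.60 for Ywhaz, 0.51 for Hprt, 0.31 for Eef1a1, 0.30 for Sdha, 0.18 for Actb and 0.06 for Tfrc. Those of Rplp0, Pgk1, Eef2, Polr2a and Gusb were −0.01, −0.05, −0.14, −0.26 and −0.31. In the limma fit on the linear scale B2m and Tbp did not pass (adjusted p = 0.0581 and 0.0542), while Eef1a1 did (0.0499). None of the 6 sex-linked genes passed, and none did so adjusted over the list alone (camera adjusted p = 0.162). Xist, made from the inactive X, lay between 7.10 and 8.13, and the Y-linked genes Eif2s3y, Kdm5d and Uty had fitted differences of 0.36, 0.05 and 0.10, with Kdm6a at 0.03 and Kdm5c at 0.36. Signals of Uty lay between 3.28 and 3.48, the level of the poly-A spikes, so its difference says little.

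Over the 41 lists, 11 were higher in colon and 19 in whole mouse by camera, and none passed with an estimated correlation, where the lowest adjusted p was 0.204. The estimated correlation between residuals was 0.806 in colonocyte genes. High correlation does not account for every loss, since lists below the preset 0.01 failed too. Among them were neurons and brain (0.003) and bone (−0.06), with camera adjusted p of 5.1e-06 and 0.0095 at the preset. The test itself was weaker with an estimated correlation. In simulated data with independent noise, a list of 20 genes shifted by 1 log2 had a camera p of 9.3e-04, against 8.6e-34 at the preset. By fry the colonocyte and goblet lists had an adjusted p of 0.0661 and the enteroendocrine list of 0.0773. Fry passed 5 lists that camera did not, with adjusted p of 0.0206 for plasma and B cells, 0.00452 for macrophages and mast cells, 0.047 for enteric neurons and glia, 0.0386 for fatty acid oxidation and 0.0065 for ribosomal proteins. A fit on the linear scale, tried after seeing the data, moved the members past the threshold both ways. Rises went from 9 to 18 in colonocyte genes and from 6 to 10 in goblet cell genes, and falls from 29 to 37 in skeletal muscle genes and from 22 to 29 in liver genes. Falls went from 24 to 19 in matrix genes, from 13 to 9 in fat genes and from 12 to 7 in erythroid genes. In ribosomal protein genes 3 fell on that scale, and in oxidative phosphorylation genes 3 rose and 1 fell.

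The undiluted arrays were compared by size alone. At least 2-fold apart were 3616 probe sets, 1853 higher in colon and 1763 in whole mouse, and 2804 of them (77.5%) also passed the test along the dilution. At 4-fold these numbers were 590 and 737. Among the named genes, Igha was 6.78 log2 higher in colon, Hoxb13 5.42 and Car8 4.01, whereas the log2 difference of Kng1 was −7.89, of Acta1 −7.32 and of Alb −7.22. Bright signals of Igha, Acta1 and Alb changed little between mixes, with Igha at 12.79 in the 25% mixture and 13.59 in colon, Acta1 at 13.95, 13.91 and 13.60 and Alb at 13.70, 13.63 and 13.45 at 0%, 25% and 50% colon, so these differences are given as measured signals, not as exact ratios of RNA. Of the 3616 probe sets, 2502 (69.2%) had all 5 values in strict order of colon share, and 85.4% of those 4-fold apart did. Since the probe sets were chosen by the end arrays, the value for chance is that of 3 mixtures in random order between them, 16.7%. With ties allowed, an alternative added after the data were seen, the share was 73.8%. The labelled order gave 4409 probe sets past the threshold and none of the other 59 of 60 orders gave any in the limma test; at an unadjusted p under 0.05 the labelled order gave 7866 and the highest other order 6850, in which the 50% and 75% mixtures changed places.

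Over all probe sets that differed 2-fold, the mixtures gave estimated colon shares above the nominal ones, but not in every set of genes. The estimated share was 40.1% (95% bootstrap interval 39.5 to 40.8) for the 25% mixture, 62.6% (62.2 to 63.2) for the 50% mixture and 78.3% (77.7 to 78.8) for the 75% mixture, over 3616 probe sets. Probe sets higher in colon gave 43.1%, 62.6% and 73.2%, and those higher in whole mouse 35.9%, 62.7% and 80.6%, so the former lay below nominal (72.1 to 74.5) in the 75% mixture. The odds of the estimated share were 2.01, 1.68 and 1.20 times the nominal odds, and the best single ratio was 1.71 (1.68 to 1.75), which would give 36.3%, 63.1% and 83.7%. Genes of colonocyte and goblet cell lists, taken without regard to their values, gave 49.1%, 73.3% and 88.3%. Genes of muscle, heart, liver, epidermis and cartilage lists gave 27.4%, 57.6% and 78.8%, with an interval of 23.7 to 31.0 at 25% that includes the nominal share. The intervals cover the choice of probe sets or genes, not the error of an array, and this split by lists was chosen after the data were seen.

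**Figure D3:**
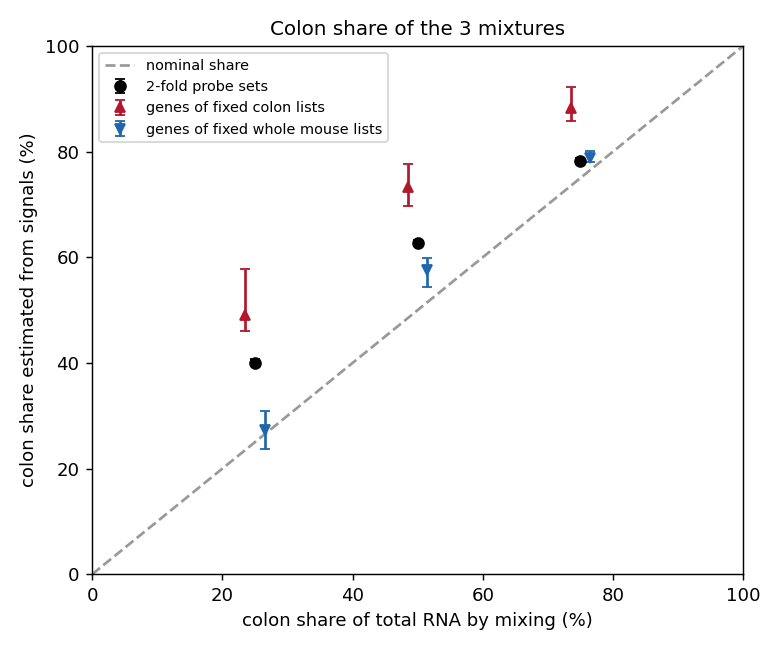
Colon share estimated from the signals in percent (vertical axis) against the share mixed by total RNA in percent (horizontal axis) for the 3 mixtures, with 95% bootstrap intervals over probe sets or genes; list genes are shifted sideways by a small step. Genes of colon lists lie at 49.1%, 73.3% and 88.3%, above genes of whole mouse lists at 27.4%, 57.6% and 78.8%.

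Signals of the mixtures lay closer to linear mixing of intensities than to a line on the log2 scale. The deviation from linear mixing at the nominal shares had a standard deviation of 0.25, 0.23 and 0.18 log2 in the 25%, 50% and 75% mixtures, against 0.37, 0.36 and 0.32 around the log2 line. Within 0.5 log2 of linear mixing lay 94.4%, 95.2% and 98.4% of all probe sets, and 82.3%, 89.7% and 93.4% of those that differed 2-fold.

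Control probe sets were not part of the tests. The 27 probe sets of poly-A spikes lay near the floor, with medians between 3.24 and 3.54 log2. The difference between the 3′ and 5′ probe sets of actin, which grows as RNA or its copies shorten, was 1.20 log2 in whole mouse and 1.86 in colon, and that of Gapdh lay between 1.41 and 1.68. For pyruvate carboxylase it was 3.35 in whole mouse and 2.39 in colon.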

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

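The tests of the spikes, of selection, of compression and of the 2 tissues' genes were chosen after the results were seen, as was the count over orders; the ratio across mixtures in fixed lists was stated beforehand. Its reading was changed to undecided after its result was seen, because 2-fold probe sets and fixed lists went apart, and the bound for the 2 tissues' genes was also changed after the results were seen.

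A signal outside the main measurement stood out. The 18 hybridisation spike probe sets, bacterial and phage sequences added to every array, were brighter on the 25% array than on the whole mouse array by a median of 0.75 log2, in 18 of 18. On the 50%, 75% and colon arrays the median differences were 0.28, 0.15 and 0.03, and the 3 probe sets of 18S rRNA were 0.46 brighter on the 25% array. No shift of the whole array was left after the normalization, as the other probe sets lay at a median of −0.055 log2 from linear mixing there. Quantile normalization brings this value near 0 in any case, so it cannot show whether the 25% array was dimmer before and was scaled up. Less labelled target on the 25% array may be the cause, but this cannot be told apart from a larger dose of spikes. Signals before normalization were not used here, and the spread around linear mixing does not decide it. At the nominal shares that spread was largest on the 25% array (0.25 log2 against 0.23 and 0.18). With estimated mRNA shares it was 0.22 against 0.21 and 0.19 over all probe sets, but 0.26 against 0.25 and 0.29 in 2-fold probe sets. No biological explanation was tested.

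The estimated colon shares of 40.1%, 62.6% and 78.3% over 2-fold probe sets exceed the mixed shares. At 50%, selecting probe sets on the undiluted arrays cannot be the whole cause, since those chosen by the 25% and 75% arrays gave 59.9% (59.0 to 61.2; 62.7% at 0.5 log2, the threshold run first), nor can compression of bright signals, since probe sets higher in whole mouse also gave 62.7% there. At 25% selection cannot be told apart from a real excess. Genes of 7 fixed lists gave 33.7% (30.9 to 36.0), the colon lists alone 49.1% (46.1 to 57.8) and the whole mouse lists alone 27.4% (23.7 to 31.0). Probe sets chosen by the 25% and 75% arrays gave 28.2%, but that choice used the 25% array itself, so it cannot decide. A colon pool with more mRNA per total RNA, acting alike on genes of both tissues, is argued against as the only cause, since at 50% colon lists gave 73.3% (69.8 to 77.6) and whole mouse lists 57.6% (54.3 to 59.9) and intervals lay apart in 5 of 6 such comparisons, all but 2-fold probe sets at 50% (62.6% and 62.7%), though not in 1 direction: genes higher in colon gave the larger share in 4 and the smaller in 2-fold probe sets at 75% (73.2% and 80.6%). Whether 1 ratio held across the mixtures cannot be told apart, as the odds ratio at 25% over that at 75% was 1.13 (0.99 to 1.25) in fixed lists but 2-fold probe sets gave 2.01 and 1.20, and a higher mRNA content of adult colon together with compression, or an error in the RNA amounts, remains an untested hypothesis.

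In the count over orders, 1 of 60, the labelled one, gave as many probe sets changing along the dilution. This is the smallest share that 60 orders of unreplicated arrays can give, so it does not exclude chance for the calls. The labelled order gave 4409 and the highest other order 0. At an unadjusted p under 0.05 the gap was small, 7866 against 6850 for the order with the 50% and 75% mixtures exchanged.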

How the results depend on the processing

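Ties, the linear scale for lists, a 0.5 log2 threshold between mixtures and the 2-fold subset for linear mixing were tried after seeing the data. No call changed direction in any alternative, although the median of the T cell list, which did not pass, went from −0.08 to 0.00 with centring, and every probe set called in both the original and an alternative fit had the same sign. Against 4409 probe sets (1953 rising, 2456 falling), unmoderated regression gave 234 (39, 195) and a threshold of 0.01 gave 932 (101, 831). Leaving out an array gave 997 to 2998 (168 to 1306 rising, 829 to 1692 falling). Rises and falls were 3148 and 2325 with median-centred arrays and 2971 and 2577 with quantile normalization. With estimated mRNA shares as the covariate 5561 probe sets passed (2856, 2705), and without dim probe sets the split was 2129 and 2123. Falls outnumbered rises in all other alternatives, so the excess of falls depended on the processing. At 4-fold the undiluted arrays differed in 1327 probe sets (590, 737). The ordered share was 73.7% with centring, 72.9% with quantile normalization, 71.9% without dim probe sets, 85.4% at 4-fold and 73.8% with ties. Estimated shares at 25%, 50% and 75% were 28.2%, 59.9% and 82.1% when chosen by the mixtures at 2-fold, 31.4%, 62.7% and 84.3% at 0.5 log2, and 38.4%, 60.8% and 76.8% with centring. They were 37.8% and 79.7% (25% and 75%) at 4-fold, 43.1% and 73.2% in colon-higher and 35.9% and 80.6% in whole-mouse-higher probe sets, and 39.4% and 61.1% (25% and 50%) by least squares. The spread around mixing was 0.22, 0.21 and 0.19 with estimated mRNA shares, 0.37, 0.36 and 0.32 around the log2 line and 0.37, 0.32 and 0.27 in 2-fold probe sets. With an estimated correlation 0 of 41 lists passed, against 30. The cause of these shifts was not tested, except where stated. Of the 122 named genes that passed, between 34 and 57 did so without 1 array. On the linear scale 6 of the 122 did not pass, and 7 other named genes did. No paired analysis was possible because each mix had 1 array. Signals near the floor, such as poly-A spikes, limit what can be said of dim genes.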

Other observations

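Gene families not fixed beforehand were looked at through shared symbol stems, and both the families and the genes named were chosen after their values were seen. Of 130 families with at least 10 measured genes, 3 passed by camera, all lower in colon: keratins, late cornified envelope genes and keratin-associated proteins. Of 40 keratins, 26 fell with colon share and 2 rose (median −1.28 log2, adjusted p = 2.9e-06), and 15 of the 40 were already in a fixed list. The fitted log2 differences of the epidermal and hair keratins Krt16, Krt6b, Krt17 and Krt35, which fell, were −2.73, −3.21, −3.75 and −2.22, whereas the simple-epithelium keratins Krt18 and Krt7 rose by 1.33 and 1.12. Krt20, Krt19 and Krt8, also of simple epithelium, had 7.86, 9.71 and 11.23 in whole mouse and 13.02, 13.56 and 13.90 in colon (adjusted p = 0.0932, 0.108 and 0.125). Of 11 late cornified envelope genes 9 fell (median −4.28, adjusted p = 4.1e-04), and of 26 keratin-associated proteins of hair 6 fell (median −0.49, adjusted p = 0.0109). With an estimated correlation the adjusted p of these 3 families was 0.991.

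Of 1327 probe sets at least 4-fold apart between the undiluted RNAs, 321 missed the threshold along the dilution, 260 of them higher in colon and 61 in whole mouse. The test of bending was chosen after the results were seen, in place of one stated beforehand whose outcome the choice of probe sets fixed, and that of noise before. Whether bending of a linear mixture on the log2 scale was the cause cannot be told apart over the 321 as a whole. As noiseless mixtures of the undiluted arrays at the nominal shares, 18.7% of the 321 missed the threshold, against 1.29% of the 1006 that passed. Of the 61 higher in whole mouse 46 (75.4%) missed in this way, so bending alone was enough for these. Of the 260 higher in colon 14 did. The estimated shares, which differed from the nominal ones, were not tried, so this leaves the 260 undecided. On the linear scale 164 of the 321 (51.1%) passed, 118 higher in colon and 46 in whole mouse. Noise between the arrays may add to the misses, since 65.4% of the 321 had all 5 values in strict order against 91.7% of those that passed. Values out of order also lower the chance of passing, however. No biological explanation was tested.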
